A study of Homo sapiens with 7 samples.

How the data were processed

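RNA of DG75-eGFP cells, DG75 B cells with an eGFP plasmid, was labelled with 4sU and separated into tagged and untagged RNA, per the labels' protocols. Of the 7 libraries, 5 held newly transcribed RNA (5, 10, 15, 20 and 60 min of labelling), 1 total RNA and 1 untagged RNA (60 min each), with 1 library per group. The libraries were made with the WTAK protocol and sequenced as 35 nt SOLiD reads without depletion of rRNA, per the labels. Reads were mapped with Bowtie to GRCh37/hg19, per the submitters' processing notes; its version and the annotation release are not given in the sources used here.

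Each deposited file held 551556 rows, for 37804 genes, 275778 exons and 237974 introns. Read counts per feature are the authors' whole-number values as deposited, with no normalisation and no separation by strand since the strand column is empty, so reads of antisense and overlapping genes could not be told apart. RPKM values are the authors' values as deposited, that is, reads scaled by the length of the feature and by the depth of the library. From the values, exon and intron rows were scaled to a total over exon and intron reads, and gene rows used a larger total. Gene rows also held reads beyond their exon rows, from 8.26 to 15.0% of reads in genes of several exons and from 0.0169 to 0.0346% in genes of a single exon; the sources used here do not say what these reads are.

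Gene rows were named from a table of gene identifiers and GENCODE release 29, of which names, biotypes and strands were used and no coordinates. Of the gene rows 31386 were named, 18551 of them protein-coding, and 6418 (17.0%) matched no name. Depth ranged from 667465 reads on gene rows in untagged RNA to 946471 in newly transcribed RNA at 60 min. The floor for a count of 0, set at 3 counts per library, was 1.03 RPKM for 1 kb of exons at 5 min and 3.96 RPKM in untagged RNA. Intervals are 95% intervals, by the Wilson method for shares of reads, exact Poisson for counts, Clopper-Pearson for the ratio of 2 counts, and 500 bootstrap draws over genes for pooled intron ratios.

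With single libraries no test between conditions was made. Gene ratios were log2 ratios of gene-row RPKM plus a pseudocount of 1, which understates differences of low genes, over genes with RPKM of 1 or more in either library, centred on the median gene. Over the 5 labelling times, ratios to 60 min were centred on the median of genes with RPKM of 1 or more in any of these libraries. A gene was counted as higher or lower past a log2 ratio of 1 (2-fold). For single genes the text gives, unless stated, the ratio of reads without a pseudocount on the same centring. Simulated libraries that differed by counting error alone gave the number of genes past the rule by chance of sampling. A list's median was placed among 10000 random lists of the same size, matched in 20 bins of mean log2 RPKM, and its place was called apart in the lowest or highest 2.5%.

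The gene lists, fixed before the data were examined, held immediate early and labile regulators, NF-kappaB targets, cytosolic ribosomal proteins, glycolysis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded genes, replication-dependent histones, non-coding snoRNA hosts, nuclear-retained long non-coding RNAs, proteasome subunits, B cell identity, ZNF-named zinc finger genes, splicing regulators, S phase and mitosis, p53 targets, heat shock genes, MYC-responsive nucleolar genes, short non-coding RNAs and markers of other cell types. Genes named in the text were the 8 highest and 8 lowest protein-coding genes with RPKM of 10 or more in at least 1 of the 2 libraries, and the 3 members of each list with the highest mean RPKM. Introns named were the 8 highest and 8 lowest in change from 5 to 60 min, among introns of 500 nt or more with RPKM of 1 or more at 5 min in genes of RPKM 10 or more in every newly transcribed library, and the 8 with the highest ratio in total RNA; 1 intron that the rule takes is not reported here. For snoRNA hosts, the reads of gene rows of 300 nt or less that overlap any exon row of the host were also taken off in each library, with its exonic length kept.

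The 3 fractions at 60 min were joined by least absolute deviations over genes with RPKM of 5 or more in each, as a weighted sum of the new-to-total and untagged-to-total ratios equal to 1. A half-life followed from the new share under exponential decay, with no correction for growth. Intron ratios were intron RPKM over gene RPKM, for introns of 100 nt or more that overlapped no exon, in genes with RPKM of 1 or more in every newly transcribed library. First, middle and last introns were compared in genes of at least 3 introns. The alternatives tried were pseudocounts of 0.1 and 5, no filter and a filter of RPKM 5, no centring or a mean trimmed by 30% on each side, protein-coding genes of 500 nt or more, exon rows in place of gene rows, other fits of the fractions, and other intron filters and summaries.

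The rule of size, the list places, the 3-fraction fit and the pooled intron ratio were tested on simulated data. Orders over the labelling times, the removal of short RNA rows and ratios to adjacent exons were not. Changes were put only into genes with 50 or more reads in the 2 libraries together. Recovery of changes in genes with fewer reads was not simulated. Of 100 genes moved by a log2 of 1.5 per comparison, 81% passed the rule in newly transcribed against total RNA. The share was 91% in untagged against newly transcribed RNA and 81% in 5 against 60 min, and 100% of those moved by 2.5 passed the rule in each. Unchanged genes passed it in 16.3, 19.6 and 12.7% of cases (18728, 18579 and 18210 genes), and in 0.159, 0.375 and 0.0430% with 50 or more reads (6276, 5861 and 6982 genes). Of 40 random lists of 30 genes per comparison, 7.5, 0 and 7.5% lay in the lowest or highest 2.5% at either end. In the simulated 3-fraction fit of 3718 genes, weights of 0.35 and 0.55 came back as 0.364 and 0.516, and a median half-life of 1.81 h came back as 1.71 h, with a Spearman rho of 0.896 between half-lives put in and recovered. The simulated fractions added up exactly apart from counting error, so this recovery does not show how well the real fractions do. A kept intron share of 40% came back as 40.1% (39.95 to 40.2%; 10225 genes). Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.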

Results

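RNA made during labelling pulses of up to 60 min was followed in DG75-eGFP cells, that is, DG75, an established human B cell line derived from a Burkitt lymphoma, with an eGFP plasmid, per the labels. 4-thiouridine (4sU), a uridine analogue that is built into RNA during transcription, was added at 500 uM, for 5 min in the shortest pulse and 60 min in the longest. RNA was then separated into a tagged, newly transcribed part and an untagged part made before the pulse. Newly transcribed RNA was sequenced at each of the 5 times, and total and untagged RNA at 60 min, with 1 library in each of the 7 groups. There were no replicates, so no difference between libraries has a replicate check and no p-value is given. Intervals are 95% intervals for counting error only, except those of pooled intron ratios, which come from bootstrap draws over genes. PCR copies of reads are not independent molecules, so intervals that count each read as independent can be too narrow.

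Gene rows held 772081 reads at 5 min, 744803 at 10 min, 711953 at 15 min, 845960 at 20 min and 946471 at 60 min of labelling, 831579 in total RNA and 667465 in untagged RNA. For a gene with 1 kb of exons, 1 read was worth 0.342 RPKM at 5 min and 1.32 RPKM in untagged RNA, the least deeply covered library. B cell identity genes had a median of 18.0 RPKM in total RNA, and CD74, the invariant chain of class II antigen presentation, reached 589.9 RPKM. Markers of other cell types stayed low there. Median RPKM was 0.639 for T cell, 0.383 for monocyte or macrophage, 2.28 for plasma cell, 0.329 for erythroid and 0.627 for epithelial or fibroblast markers, among which VIM reached 14.2 RPKM.

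Unspliced and mitochondrial RNA divided the libraries. Introns took 74.3% (95% Wilson interval 74.2 to 74.3%) of the reads on gene and intron rows at 5 min, 70.4% (70.3 to 70.5%) at 10 min, 63.3% (63.2 to 63.4%) at 15 min, 58.3% (58.2 to 58.4%) at 20 min and 52.7% (52.7 to 52.8%) at 60 min. The share was 30.4% (30.3 to 30.5%) in total and 14.6% (14.5 to 14.65%) in untagged RNA. The 2 mitochondrial rRNAs took 7.97% (7.91 to 8.03%) of gene reads at 5 min, 14.6% (14.5 to 14.7%) at 15 min and 14.0% (13.9 to 14.1%) at 20 min. They took 12.4% (12.4 to 12.5%) at 60 min and 25.8% (25.7 to 25.9%) in total RNA. Mitochondrial mRNAs went from 2.27% (2.23 to 2.30%) at 5 min to 5.10% (5.05 to 5.14%) at 20 min. They fell to 3.70% (3.66 to 3.74%) at 60 min and stood at 2.79% (2.76 to 2.83%) in total RNA. snoRNAs, short guide RNAs for rRNA modification, took 0.177% (0.168 to 0.187%) of gene reads at 5 min and 0.147% (0.140 to 0.155%) at 60 min, against 2.40% (2.37 to 2.44%) in total and 3.68% (3.64 to 3.73%) in untagged RNA. Long non-coding genes took 5.25% (5.20 to 5.30%) at 5 min and 2.27% (2.24 to 2.30%) in total RNA. Replication-dependent histone genes took 0.122% (0.115 to 0.130%) at 5 min, 0.261% (0.251 to 0.272%) at 60 min and 0.167% (0.159 to 0.176%) in total RNA.

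Newly transcribed RNA at 60 min was set against total RNA to order genes by turnover. Coordinates are 1-based and refer to GRCh37/hg19. Labile regulators lay on the newly transcribed side. MYC, the transcription factor whose locus is rearranged in Burkitt lymphoma (ENSG00000136997, chromosome 8, 128747680 to 128753674), had a centred log2 ratio of 1.65 (counting interval 1.43 to 1.88) on 984 reads against 195. NFKBIA, the NF-kappaB inhibitor that NF-kappaB itself induces (ENSG00000100906, chromosome 14, 35870717 to 35873952), stood at 2.11 (1.64 to 2.62), and DUSP2, a phosphatase of MAP kinases (ENSG00000158050, chromosome 2, 96808905 to 96811179), at 2.39 (1.70 to 3.16). At the other end, GAPDH of glycolysis (ENSG00000111640, chromosome 12, 6643093 to 6647537) stood at −1.64 (−1.75 to −1.54) and RPS2 of the small ribosomal subunit (ENSG00000140988, chromosome 16, 2012062 to 2014861) at −1.69 (−1.88 to −1.51).

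Of 38 measured immediate early and labile regulators, 23 were at least 2-fold higher in newly transcribed RNA and 0 at least 2-fold lower. Their median log2 ratio of 1.23 lay at percentile 100 of 10000 random lists of equal size and mean expression, a description of these libraries. MCL1, an anti-apoptotic protein, stood at 1.22 (0.90 to 1.55) and ID3, an inhibitor of helix-loop-helix factors, at 1.33 (0.85 to 1.85). Of 391 zinc finger genes, 54 were higher and 4 lower (median 0.46, percentile 100), with ZNF639 at 0.73 (0.32 to 1.16) and ZNF146 at 0.44 (0.07 to 0.81). p53 targets had a median of 0.51 (percentile 99.2), and 3 of 14 were higher, among them PMAIP1, a pro-apoptotic BH3 protein, at 1.30 (0.95 to 1.67). MDM2, the ligase that degrades p53, stood at 0.69 (0.48 to 0.89). NF-kappaB targets had a median of 0.40 (percentile 99.3) with 2 of 18 higher; among genes of RPKM 5 or more the percentile was 91.35. BIRC3, an apoptosis inhibitor, stood at 0.36 (0.08 to 0.66). Splicing regulators had a median of 0.27 (percentile 100), with 2 of 35 higher and 1 lower, and DDX5, an RNA helicase, at 0.21 (0.03 to 0.39).

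Housekeeping genes lay on the side of total RNA. Of 79 cytosolic ribosomal protein genes, 48 were at least 2-fold lower in newly transcribed RNA and 0 higher; their median of −1.29 lay at percentile 0.795, but at 30.15 among genes of RPKM 5 or more. RPLP0, a stalk protein of the large subunit, stood at −0.57 (−0.71 to −0.42). Nuclear genes of oxidative phosphorylation had a median of −0.85 (percentile 0) with 34 of 78 lower. ATP5F1B and ATP5F1A of the ATP synthase stood at −1.21 (−1.42 to −1.002) and −1.25 (−1.44 to −1.06), and COX4I1 of cytochrome oxidase at −1.502 (−1.95 to −1.06). Glycolysis genes had a median of −0.99 (percentile 4.48, but 0.05 on protein-coding genes of 500 nt or more) with 8 of 17 lower, among them LDHB at −1.49 (−1.68 to −1.29) and LDHA at −1.46 (−1.62 to −1.31), which interconvert pyruvate and lactate. Proteasome subunits had a median of −0.59 (percentile 3.37, but 0.25 on those genes and 1.55 among genes of RPKM 5 or more) with 11 of 36 lower, PSMA4 standing at −0.95 (−1.37 to −0.53). B cell identity genes had a median of −0.23 (percentile 69.6) with 4 of 33 lower and 1 higher. The 4 included CD74 at −1.09 (−1.22 to −0.95) and HLA-DRA, the class II alpha chain, at −1.25 (−1.45 to −1.05).

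Several groups sat near the median gene, and mitochondrially encoded, histone and S phase genes among them above lists of like expression. Mitochondrially encoded genes had a median of −0.06 (percentile 99.6; 0.06 among genes of RPKM 5 or more), with MT-CO1 of cytochrome oxidase at −0.26 (−0.30 to −0.21) and MT-CO2 at −0.77 (−0.84 to −0.69). Replication-dependent histones had a median of 0.06 (percentile 99.9; −0.01 without centring), with 2 of 27 higher and 4 lower. H4C3 stood at −1.53 (−1.89 to −1.18) and H2BC11 at 0.42 (0.01 to 0.85). S phase and mitosis genes had a median of −0.03 (percentile 99.1; 0.09 among genes of RPKM 5 or more), with PCNA, the replication clamp, at −0.86 (−1.21 to −0.51). MYC-responsive nucleolar genes had −0.02 (percentile 97.495; 0.07 and percentile 98.65 among genes of RPKM 5 or more, and percentile 97.75 with a pseudocount of 0.1 or a trimmed mean), with NPM1 at −1.89 (−2.05 to −1.73) and nucleolin, NCL, at −0.49 (−0.62 to −0.35). Heat shock genes did not lie apart at −0.04 (percentile 93.5; 0.03 among genes of RPKM 5 or more), with 3 of 12 higher, HSPA8 at 0.44 (0.32 to 0.56) and HSP90AB1 at −0.74 (−0.84 to −0.65).

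Non-coding host genes of snoRNAs had a median of 0.35 (percentile 99.99), with 2 of 12 higher and 4 lower. Without the reads of short RNA rows that overlap their exons, an alternative chosen after the data were seen, the median was 0.67 (percentile 100), with 3 higher and 0 lower. SNHG3 stood at 0.50 (0.32 to 0.69) with those reads and at 1.23 (0.99 to 1.46) without them, and GAS5 at −2.31 (−2.41 to −2.21) and 0.75 (0.56 to 0.94). Nuclear-retained long non-coding RNAs had a median of 0.27 (percentile 92.3), and of 0.64 (percentile 99.6) among genes of RPKM 5 or more. MIR17HG, the primary transcript of a microRNA cluster, stood at 2.29 (1.23 to 3.57), NEAT1, the scaffold of paraspeckles, at 0.83 (0.62 to 1.04) and MALAT1, a speckle RNA, at −0.97 (−1.08 to −0.86). The mature snoRNA SNORD34 (chromosome 19, 49994161 to 49994231) stood at −6.33 (−6.76 to −5.93) on 51 reads against 2563, while SNORA1 had 19 against 1. Short and multi-copy RNAs are poorly counted with 35 nt reads.

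Among protein-coding genes of RPKM 10 or more in either library, ID2, another inhibitor of helix-loop-helix factors, at 2.24 (1.48 to 3.09), VCPKMT, a lysine methyltransferase, at 2.58 (1.26 to 4.27), ZFP36, which promotes decay of AU-rich mRNAs, at 2.45 (0.96 to 4.40) and ZNF574 at 2.27 (1.399 to 3.27) were with DUSP2 and NFKBIA among the 8 highest. The histone gene H2AC25 had 13 reads against 1, a log2 ratio of 3.02 (0.28 to 8.43), and TIAF1 had 7 against 0, with a lower counting limit of −0.16, so that no difference was detectable at this depth. The 8 lowest were RPL13A at −3.31 (−3.42 to −3.20), HRC at −4.17 (−5.34 to −3.19), KISS1R at −4.24 (−5.92 to −2.94), CDH19 at −5.02 (−6.67 to −3.75), DPYS at −3.75 (−4.87 to −2.80), TBC1D24 at −3.50 (−4.03 to −3.01), LBR at −3.31 (−3.56 to −3.06) and ENSG00000251357 at −3.85 (−7.00 to −1.79). One exon row held 100% of total RNA reads in HRC and KISS1R, 95.05% in CDH19, 98.8% in DPYS, 97.8% in TBC1D24 and 91.2% in RPL13A, whose exon holds 4 annotated snoRNAs. In LBR, 88.1% lay beyond the exon rows, and in ENSG00000251357 the fullest exon row held 33.3%.

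Over 20041 genes, 2841 were at least 2-fold higher and 2933 at least 2-fold lower in newly transcribed RNA, where counting error alone gave 1451 and 1126 in simulated libraries. Of 6478 genes with 50 or more reads in the 2 libraries together, a filter chosen after the data were seen, 218 were higher and 542 lower; centred on these genes, 27.4% of those past the rule were higher, against 49.2% with all genes. Among genes of RPKM 5 or more the counts were 898 and 1434, or 38.5% higher.

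**Figure D1:**
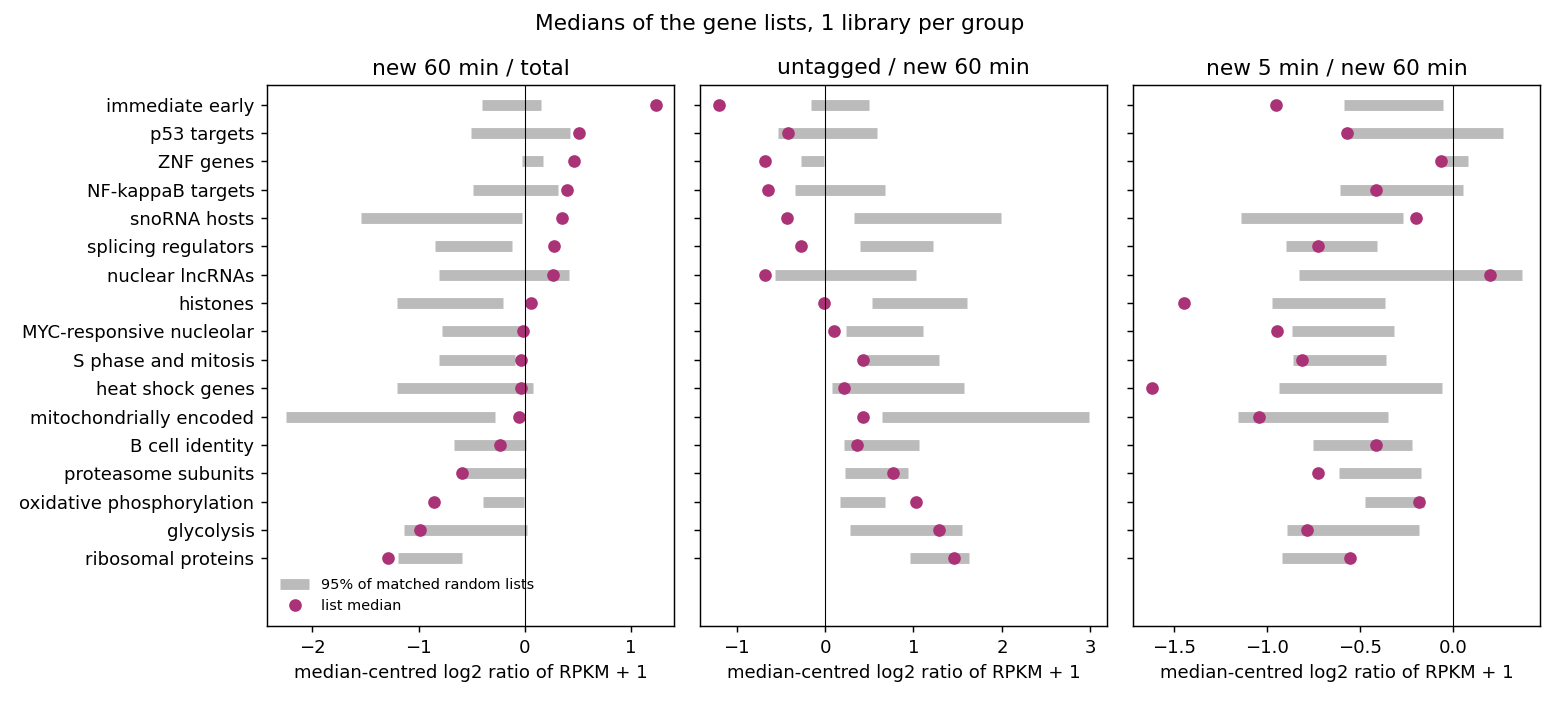
Medians of 17 gene lists in 3 comparisons of single libraries, as median-centred log2 ratios of RPKM + 1 on the x axis; points are list medians and grey bars span 95% of 10000 random lists of the same size and mean expression. Immediate early genes lay at 1.23 in newly transcribed against total RNA and at −1.20 in untagged against newly transcribed RNA, and heat shock genes at −1.62 in 5 against 60 min.

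Untagged RNA, made before the pulse, was set against newly transcribed RNA at 60 min. Both this comparison and that with total RNA use the newly transcribed library of 60 min, so their values are not independent. MYC had a log2 ratio of −1.96 (−2.26 to −1.68), NFKBIA −1.93 (−2.4998 to −1.41) and PMAIP1 −1.67 (−2.16 to −1.21). GAPDH stood at 1.95 (1.84 to 2.06), RPS2 at 2.13 (1.94 to 2.31) and NPM1 at 2.06 (1.90 to 2.23). Of 42 measured immediate early genes 25 were at least 2-fold lower in untagged RNA and 0 higher (median −1.20, percentile 0). NF-kappaB targets had 8 of 18 lower and 1 higher (median −0.64, percentile 0.09) and zinc finger genes 121 of 396 lower and 7 higher (median −0.67, percentile 0). Splicing regulators had a median of −0.27 (percentile 0), long non-coding RNAs −0.68 (percentile 1.28), p53 targets −0.42 (percentile 5.37, but 2.35 on protein-coding genes of 500 nt or more) and snoRNA host genes −0.43 (percentile 0), with 4 of 12 higher and 2 lower. Without the short RNA rows in their exons the hosts had −0.97 (percentile 0), with 0 higher and 5 lower. NEAT1 stood at −1.44 (−1.74 to −1.16), MALAT1 at 1.43 (1.32 to 1.54), and GAS5 at 3.04 (2.94 to 3.14), or −1.69 (−1.99 to −1.40) without those rows.

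On the untagged side, 57 of 79 ribosomal protein genes were at least 2-fold higher and 0 lower, with a median of 1.46 (percentile 87.4, but 100 on protein-coding genes of 500 nt or more). Oxidative phosphorylation had 42 of 79 higher and 4 lower (median 1.02, percentile 100), and glycolysis 11 of 17 higher (median 1.29, percentile 89.9, but 99.4 on those genes), with PKM, the last enzyme of the pathway, at 1.83 (1.67 to 2.002). Proteasome subunits had 13 of 36 higher (median 0.77, percentile 85.7), PSMA3 standing at 1.86 (1.29 to 2.44). B cell identity genes had 8 of 33 higher and 1 lower (median 0.37, percentile 10.5), CD79A of the B cell receptor standing at 1.96 (1.46 to 2.48). Mitochondrially encoded genes had a median of 0.42 (percentile 0.47), MT-CO1 standing at 0.78 (0.74 to 0.83), and S phase genes of 0.43 (percentile 3.54). Histones had −0.01 (percentile 0; 0.15 without centring), with H4C3 at 2.34 (2.00 to 2.69). MYC-responsive nucleolar genes had 0.10 (percentile 0.30) and heat shock genes 0.22 (percentile 6.72); among genes of RPKM 5 or more these turned to −0.17 for both, heat shock genes then lying at percentile 1.8. HSPA8 stood at −0.43 (−0.57 to −0.29) and HSP90AB1 at 1.23 (1.14 to 1.32).

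Lowest in untagged RNA were DNAJB1, a heat shock co-chaperone, at −3.53 (−4.67 to −2.58), TIGD1 at −3.85 (−6.15 to −2.26), DDX3X, an RNA helicase, at −3.26 (−4.18 to −2.46) and DUSP2 at −3.30 (−4.64 to −2.23). ID1, TMEM86B and ZFP36 had 1 untagged read each and stood at −4.07 (−9.41 to −1.51), −4.15 (−9.48 to −1.59) and −3.92 (−9.26 to −1.35), and TRIAP1 had 0 untagged reads against 11, with an upper counting limit of −0.12. Highest were RPL13A at 4.36 (4.25 to 4.46), DPYS at 4.75 (3.82 to 5.85), TBC1D24 at 4.51 (4.02 to 5.03), GPC2 at 4.95 (3.92 to 6.20), OR4D9 at 4.15 (2.92 to 5.67), LBR at 3.82 (3.58 to 4.08), LZTR1 at 4.28 (3.70 to 4.92) and HRC at 4.02 (3.003 to 5.21). One exon row of LZTR1 (chromosome 22, 21342299 to 21342407) held 93.4% of its untagged reads, OR4D9 has a single exon row, and in GPC2 99 of 107 untagged reads lay beyond the exon rows. Over 20096 genes 3318 were higher and 4265 lower, where counting error alone gave 1145 and 1914. With 50 or more reads in the 2 libraries together, 865 of 6061 were higher and 475 lower; with all genes 43.8% of those past the rule were higher, and centred on genes with 50 or more reads 57.8%. The median gene stood at 0.16 before centring.

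Half-lives were read from a fit that assumes that tagged and untagged RNA add up to total RNA. Over 4563 genes the weights were 0.348 for newly transcribed and 0.539 for untagged RNA. The weighted sum of the 2 ratios, set to 1 in the fit, had quartiles of 0.833 and 1.09 across genes. The addition thus held only roughly for single genes, and the half-lives rest on it. The median half-life was 2.00 h (quartiles 1.42 and 2.99 h across genes), uncorrected for cell growth, and 14 genes had none because their new share passed 100%. Immediate early genes had a median of 0.465 h over 11 of 13 fitted genes, which leaves out 2 whose new share passed 100%, p53 targets 1.07 h on 4 genes, zinc finger genes 1.18 h, splicing regulators 1.43 h, snoRNA hosts 1.53 h on 10 of 11, snoRNA reads included, and histones 1.54 h. Medians were 1.80 h for mitochondrially encoded and for MYC-responsive genes, 1.83 h for NF-kappaB targets on 8 of 9, 1.84 h for S phase genes, 1.90 h for heat shock genes on 8 of 9, 2.35 h for B cell genes and 2.59 h for 3 long non-coding RNAs. They were 3.09 h for proteasome subunits, 3.92 h for oxidative phosphorylation, 4.19 h for glycolysis and 4.82 h for ribosomal proteins. Short non-coding RNAs came to 27.0 h on 145 of 146, with quartiles of 8.22 and 68.3 h. Such values lie far beyond the 60 min pulse and rest on small new shares, such as 0.412% in SNORD34 on 51 new reads. Growth was not corrected for and recovery of short RNAs as tagged RNA was not tested, so these are not measured stabilities. The members left out, whose new share passed 100%, were SNHG15, NFKBIA, DNAJB1 and SNORA1; taken as the shortest-lived, they would give 1.41 h for snoRNA hosts, 1.67 h for NF-kappaB targets and 1.89 h for heat shock genes, and the 2 left out of immediate early genes 0.421 h. Half-lives assume constant synthesis over the pulse. Of the 3 heat shock genes whose 60 against 20 min ratio passed that of the labelling times, DNAJB1 has no half-life and HSPA1A and HSPA1B were not fitted. Among fitted genes, that ratio relative to the median gene was 2.23-fold (2.05 to 2.42) in HSPA8 and 1.22-fold (0.911 to 1.63) in HSPH1. Constant synthesis was not shown for the fitted genes. MCL1 came to 0.465 h (0.195 to 0.711 h), NEAT1 to 0.778 h (0.606 to 0.968 h), MDM2 to 0.905 h (0.721 to 1.11 h) and GAPDH to 6.16 h (5.70 to 6.66 h). These intervals hold counting error only, at a fixed weight of 0.348, which ranged from 0.285 to 0.398 over the settings tried. MYC and NFKBIA had new shares of 104.5% and 144.0% in this fit and so no half-life. The number of genes without one was 25 by ordinary least squares and from 0 to 152 with other gene filters. Across genes, which are not independent replicates, the new-to-total and untagged-to-total ratios had a Spearman rho of −0.184 in the fit, −0.0146 among genes of RPKM 1 or more and −0.366 at RPKM 20 or more; both ratios share the total RNA library, whose error moves them the same way. The median half-life lay between 1.70 and 2.73 h over the settings tried.

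The 5 min library was set against the 60 min library to compare RNA just after synthesis with RNA up to an hour old. Heat shock genes stood lowest. HSPA8, the constitutive HSP70 (ENSG00000109971, chromosome 11, 122928203 to 122932844), had a log2 ratio of −2.15 (−2.30 to −2.00), HSP90AB1 −1.85 (−1.99 to −1.72) and HSP90AA1 −1.82 (−1.99 to −1.66). MYC stood at −2.18 (−2.39 to −1.98). Of 12 heat shock genes 8 were at least 2-fold lower at 5 min and 0 higher (median −1.62, percentile 0), and of 25 histone genes 17 were lower and 0 higher (median −1.45, percentile 0). H1-4, a linker histone, stood at −1.87 (−2.28 to −1.48). Immediate early genes had 15 of 37 lower and 0 higher (median −0.95, percentile 0), MCL1 standing at −1.26 (−1.52 to −0.999). MYC-responsive nucleolar genes had 12 of 27 lower (median −0.94, percentile 0.49), with NPM1 at −1.52 (−1.78 to −1.28), and proteasome subunits 12 of 36 (median −0.73, percentile 0.10). For p53 targets the median was −0.57 (percentile 2.37), but the percentile was 3.15 with a pseudocount of 0.1 and 9.0 among genes of RPKM 5 or more.

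Ribosomal protein genes and snoRNA hosts lay above lists of like expression, and the other groups did not lie apart. S phase genes had a median of −0.81 (percentile 5.89), glycolysis −0.78 (percentile 8.97), mitochondrially encoded genes −1.04 (percentile 10.2), NF-kappaB targets −0.41 (percentile 20.6), splicing regulators −0.73 (percentile 30.1) and B cell genes −0.42 (percentile 67.8). GAPDH stood at −1.66 (−1.83 to −1.49), DDX5 at −1.79 (−2.01 to −1.58), PCNA at −1.52 (−2.02 to −1.04) and CD74 at −1.40 (−1.59 to −1.21). Ribosomal protein genes had −0.56 (percentile 98.3), with RPLP0 at −1.73 (−1.94 to −1.53). The remaining medians turned sign with scaling. Oxidative phosphorylation stood at −0.18 (percentile 95.4; 0.02 among genes of RPKM 5 or more), snoRNA hosts at −0.20 (percentile 98.6; 0.26 on that filter), zinc finger genes at −0.06 (percentile 3.33; 0.03 on that filter) and long non-coding RNAs at 0.20 (percentile 94.4; −0.22 without centring). Of these, oxidative phosphorylation lay apart on protein-coding genes of 500 nt or more (percentile 100), zinc finger genes with a pseudocount of 0.1 (percentile 0.40) and long non-coding RNAs among genes of RPKM 5 or more (percentile 98.7). SNHG3 stood at 0.19 (0.05 to 0.33), MIR17HG at 0.29 (−0.20 to 0.78) and BCL6, a germinal centre repressor, at −0.05 (−0.22 to 0.11).

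Lowest at 5 min among protein-coding genes was HSPA1B, an inducible HSP70, with 2 reads against 71, a log2 ratio of −5.31 (−8.38 to −3.40). DNAJB1 stood at −2.395 (−2.86 to −1.95), NXF1, the mRNA export receptor, at −2.92 (−3.88 to −2.07), H2AC11 at −2.29 (−2.60 to −1.99), H2AC21 at −2.48 (−4.22 to −1.07) and NKX6-3, with 2 reads against 22, at −3.62 (−6.75 to −1.595). H2AC25 and TRIAP1 had 1 read each at 5 min and stood at −3.86 (−9.27 to −1.13) and −3.62 (−9.05 to −0.84). Highest were KIF13A at 5.65 (5.19 to 6.14), ASB7 at 3.07 (2.69 to 3.48), PINLYP at 1.75 (0.59 to 3.08), UGT8 at 1.52 (1.17 to 1.89), METTL21A at 1.48 (1.25 to 1.72), CHP2 at 1.32 (0.69 to 1.99), C4orf36 at 1.28 (0.86 to 1.71) and ASTN2 at 1.16 (0.87 to 1.46). A single exon row held most of their 5 min reads, 98.7% in KIF13A, 97.0% in ASB7 and from 76.7 to 98.8% over the 8 genes. Without that exon row the ratio, with the pseudocount of 1, was 0.56 for KIF13A and −0.11 for ASB7, and 0 of the 8 stayed 2-fold higher. PINLYP was named by its identifier alone, and its row lay at chromosome 19, 11670276 to 11686372, which was not checked against an annotation of that build.

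Over 19211 genes 2855 were at least 2-fold higher and 1754 at least 2-fold lower at 5 min, where counting error alone gave 1126 and 844. The median gene stood at −0.42 before centring; without centring 1942 were higher and 4314 lower, so that 31.0% of genes past the rule were higher in place of 61.9%. Of 7189 genes with 50 or more reads in the 2 libraries together, 121 were higher and 657 lower; centred on these genes, 340 were higher and 294 lower, or 53.6% higher.

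Over all 5 labelling times, SR proteins and other splicing regulators most often stood in the order of labelling, with 22 of 35 higher at each longer time. The same order held for 13 of 43 immediate early genes, 11 of 31 S phase genes, 10 of 27 MYC-responsive genes and 5 of 12 heat shock genes. Centred on the 24111 genes of RPKM 1 or more in any of the 5 libraries, a wider set than in 5 against 60 min alone, heat shock medians against 60 min were −1.80 at 5 min, −1.47 at 10 min, −0.96 at 15 min and −0.91 at 20 min. Mitochondrially encoded genes stood on the same centring at −1.22, −0.74, 0.03 and 0.31 at those times. Over 24111 genes 1191 (4.94%) stood in rising and 891 (3.70%) in falling order of labelling, where chance gives 0.833% each. Among 7896 genes with 100 or more reads in the 5 libraries, 1024 (13.0%) stood in rising and 81 (1.03%) in falling order. The orders of lists and of all genes were not recomputed on another centring. In 5 against 60 min, genes with 50 or more reads were 121 higher and 657 lower, but 340 higher and 294 lower when centred on themselves. The excess of rising order may therefore depend on the centring.

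Of the heat shock genes, HSPA1A, HSPA1B and DNAJB1 stood apart between 20 and 60 min. HSPA1B (ENSG00000204388, chromosome 6, 31795688 to 31798031) had 2, 4, 2 and 3 reads at 5, 10, 15 and 20 min and 71 at 60 min; total RNA held 13. HSPA1A (ENSG00000204389, chromosome 6, 31783320 to 31785723) had 1 read at 20 min and 39 at 60 min. These 2 genes are near-identical copies, so the split of reads between them is uncertain. DNAJB1 (ENSG00000132002, chromosome 19, 14625582 to 14629201) had 42 reads at 20 min and 240 at 60 min. Relative to the median gene, the 60 against 20 min ratio was 23.1-fold (7.57 to 114.4) for HSPA1B, 38.0-fold (6.43 to 1538) for HSPA1A and 5.57-fold (4.00 to 7.92) for DNAJB1. The lower limit passed 3-fold, the ratio of the labelling times, in these 3 of 12 heat shock genes; it did not in HSPB1 at 2.71-fold (1.22 to 6.59), HSPH1 at 1.22-fold (0.911 to 1.63) or BAG3, with 8 reads at 20 min and 7 at 60 min. It did in 5 of 11038 genes with 20 or more reads in the 2 libraries. The others, PRKCH, a protein kinase C, with 2 against 40 reads, and GEMIN2, an snRNP assembly factor, with 1 against 20, are named after their values were seen. The lower limit was above 3-fold in 0 of 14 p53 targets, 0 of 40 immediate early genes and 0 of 26 histone genes. Tagged RNA of the median gene also builds up over the pulse, so 3-fold relative to it is stricter than steady synthesis requires. Genes below this limit, such as HSPA8 at 2.23-fold (2.05 to 2.42), are therefore not shown to have steady synthesis.

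**Figure D2:**
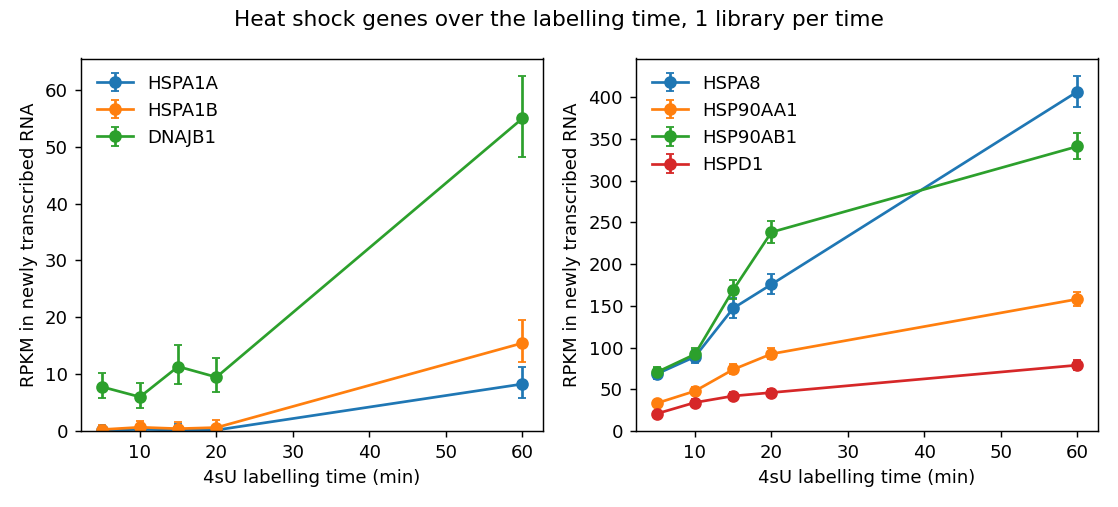
RPKM of heat shock genes in newly transcribed RNA on the y axis against the labelling time in min, 1 library per time; bars are 95% Poisson intervals for counting error. HSPA1A, HSPA1B and DNAJB1, on the left, had 1, 3 and 42 reads at 20 min and 39, 71 and 240 at 60 min.

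The intron to exon ratio was followed to see how unspliced RNA declines with labelling time. Across 102104 introns of 10225 genes, the median intron had a read density of 26.3% of its gene's exons at 5 min, 19.9% at 10 min, 15.7% at 15 min, 12.5% at 20 min and 9.74% at 60 min, and 0 in total and untagged RNA. Pooled over introns, a summary chosen after the data were seen, the ratio was 32.8% (95% bootstrap interval over genes 31.7 to 33.8%) at 5 min, 27.4% (26.7 to 28.2%) at 10 min, 22.1% (21.6 to 22.6%) at 15 min, 18.1% (17.6 to 18.5%) at 20 min and 13.6% (13.3 to 13.9%) at 60 min. Total RNA held 6.08% (5.90 to 6.29%) and untagged RNA 1.82% (1.74 to 1.92%).

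**Figure D3:**
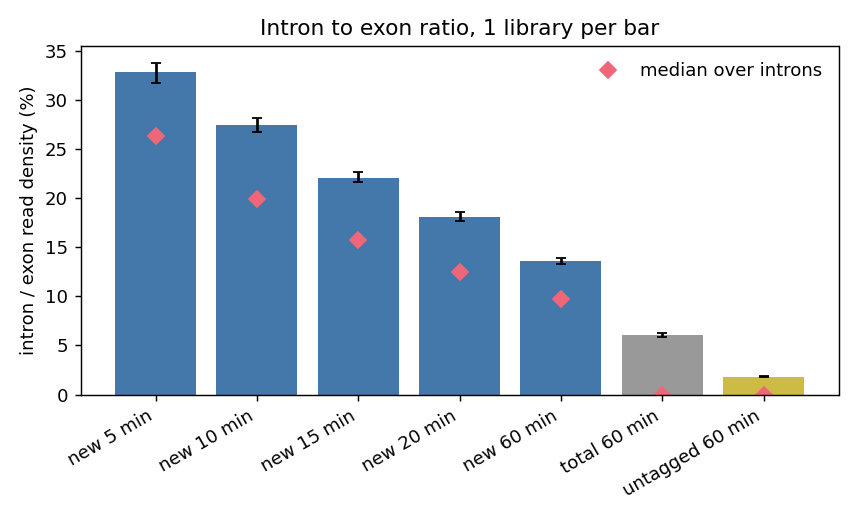
Intron read density as a percent of exon read density on the y axis, in 7 libraries on the x axis; bars are the ratio pooled over introns with 95% bootstrap intervals over genes, and diamonds the median over introns. The pooled ratio was 32.8% at 5 min, 13.6% at 60 min, 6.08% in total and 1.82% in untagged RNA.

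Gene groups differed in how much intron they held. snoRNA host genes kept 77.9% at 60 min (21.4 to 86.3%) against 70.7% at 5 min (38.0 to 73.8%), on 13 introns. These introns held 19.8% (1.62 to 26.6%) in total RNA and 2.34% in untagged RNA. Introns that overlap an exon were left out here as in the other ratios. Long non-coding RNAs went from 38.0% (27.1 to 50.5%) at 5 min to 26.6% (22.4 to 31.9%) at 60 min and 19.8% (11.5 to 27.7%) in total RNA. Splicing regulators held 48.4% (41.0 to 55.9%) at 5 min, 22.2% (18.3 to 27.1%) at 60 min and 9.89% (7.01 to 13.4%) in total RNA. Heat shock genes held 10.5% (3.74 to 40.5%) at 5 min and 4.13% (1.65 to 18.3%) at 60 min. B cell identity genes went from 53.8% (45.4 to 64.1%) to 16.8% (13.1 to 23.1%), and S phase genes from 35.5% (31.7 to 39.9%) to 10.8% (9.18 to 13.1%). In total RNA zinc finger genes held 12.2% (10.1 to 15.2%), immediate early genes 9.04% (4.17 to 19.8%), NF-kappaB targets 8.40% (6.47 to 11.6%) and p53 targets 7.92% (5.24 to 10.5%). Oxidative phosphorylation genes held 3.08% (2.17 to 4.65%), MYC-responsive genes 2.40% (1.61 to 4.57%), proteasome subunits 2.27% (1.22 to 3.92%), glycolysis genes 1.99% (1.22 to 3.37%) and ribosomal protein genes 1.65% (1.24 to 2.23%).

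Relative to the whole gene's exons, the longest introns kept least of their early signal. Introns of different length were not compared relative to the exon rows on either side. The pooled ratio at 60 min, as a percent of that at 5 min, was 47.3% (46.0 to 48.9%) in the shortest quartile of introns, 45.9% (44.8 to 47.0%) and 44.1% (43.1 to 45.3%) in the next ones and 39.99% (38.9 to 41.1%) in the longest. Among last introns the shares were 51.9, 52.98, 53.8 and 49.4% from the shortest to the longest quartile. In total RNA the pooled ratio was higher in longer introns, at 4.62, 5.25, 5.52 and 6.38%, and in untagged RNA it was 1.504, 1.63, 1.62 and 1.91%. The median log2 change from 5 to 60 min was −0.43, −0.84, −1.06 and −1.25 from the shortest to the longest quartile, and 65.2% of introns in the shortest quartile had no read at 60 min. By position, first introns kept 35.9% (34.5 to 37.3%), middle introns 41.3% (40.3 to 42.4%) and last introns 51.4% (49.1 to 53.9%), with median log2 changes of −1.05, −0.97 and −0.67. This order rests on the whole gene's exons as the reference. Relative to the exon rows on either side, first introns kept 49.1% (46.4 to 52.1%) and last introns 46.5% (43.6 to 49.3%), and the difference of −2.65 percentage points (−6.98 to 1.41) held 0.

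**Figure D4:**
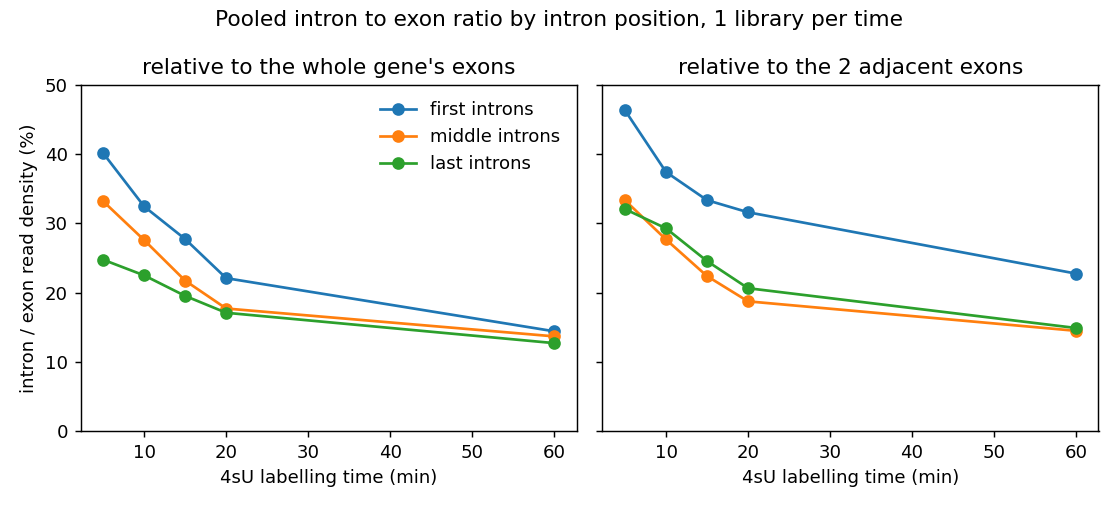
Intron to exon read density in percent on the y axis against the labelling time in min, pooled over first, middle and last introns, 1 library per time, relative to the exons of the whole gene (left) or to the exons on either side (right). Relative to the whole gene, first introns went from 40.1 to 14.4% and last introns from 24.8 to 12.7%; relative to the adjacent exons, from 46.3 to 22.8% and from 32.1 to 14.9%.

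Single introns were compared in genes of RPKM 10 or more in every newly transcribed library. Of 2917 introns of 500 nt or more, 96.4% had a lower ratio at 60 than at 5 min, 2213 by a log2 change of at least 1, while 9 were higher by as much. These introns were chosen for RPKM of 1 or more at 5 min with no such filter at 60 min, which in itself favours a lower ratio at 60 min. Among the lowest were intron 1 of TUBB, a beta tubulin (chromosome 6, 30688341 to 30689350), with 39 reads at 5 min and 1 at 60 min, a log2 change of −6.03 (−11.94 to −4.04), and intron 7 of HSPA5, the chaperone of the endoplasmic reticulum (chromosome 9, 127999434 to 128000419), with 13 and 1. Intron 32 of TOP2A, a topoisomerase, had 14 reads at 5 min, intron 9 of STK4 21, intron 6 of DDX17 9, intron 29 of PLCG2 11 and intron 16 of PRDM10 12, each against 0 at 60 min. The highest was intron 3 of COX4I1 (chromosome 16, 85838711 to 85839338), at 12.5% of its gene's exons at 5 min and 39.8% at 60 min, a log2 change of 1.57 (0.25 to 3.41). Intron 7 of RBM14, an RNA-binding coactivator, stood at 1.26 (0.30 to 2.31) and intron 7 of METTL21A at 1.20 (0.50 to 1.87). For intron 5 of METTL21A, intron 4 of RPL35A, intron 21 of FUBP1, intron 8 of TRA2B and intron 5 of MSMO1 the changes of 1.48, 1.47, 1.27, 1.08 and 1.07 had intervals that held 0.

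In total RNA 15 of 1834 introns, chosen for RPKM of 1 or more there, reached 50% or more of exon density. CIITA, the class II transactivator (intron 18, chromosome 16, 11016348 to 11017084), stood at 146.3% (88.1 to 228.5%) in total RNA and 227.5% at 5 min. TERT, the telomerase catalytic subunit (intron 11, chromosome 5, 1260716 to 1264362), stood at 83.7% (63.9 to 107.8%) in total RNA, 100.3% at 60 min and 109.8% at 5 min. Intron 3 of HNRNPH1, a splicing factor, stood at 100.5% (70.4 to 139.2%), intron 3 of CCNL1, a cyclin of the splicing machinery, at 67.6% (36.0 to 115.6%), and introns 2 and 7 of RBM14 at 116.8% (65.3 to 192.6%) and 75.3% (32.5 to 148.3%). Introns 7 and 13 of WDR43, a ribosome biogenesis factor (chromosome 2, from 29135577 to 29136934 and from 29150567 to 29152444), stood at 268.5% (226.3 to 316.2%) and 129.0% (104.3 to 157.7%) in total RNA but at 10.3 and 22.4% in newly transcribed RNA at 60 min. Reads were not separated by strand, so RNA from an overlapping or antisense gene cannot be told apart in these introns.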

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

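The tests of steady synthesis, of cell state, of reads inside an exon or beyond the exon rows, of depth, of counting error in 1 gene and of intron length were chosen only after the result was seen; those of gene span, of picking the fullest exon and of the authors' gene value were written before. Data outside the comparisons held 3 signals above the limit of a count of 0. Gene rows with unmatched identifiers took 5.36% (Wilson interval 5.31 to 5.41%) of gene reads at 5 min and 4.46% (4.41 to 4.51%) in untagged RNA. Among them ENSG00000232092 (chromosome 3, 87138430 to 87147851) held 2212 reads at 5 min, 787 at 60 min, 297 in total and 75 in untagged RNA. Introns that overlap an exon, left out of the intron ratios, held 18.8% (18.7 to 18.8%) of intron reads at 5 min and 28.1% (27.8 to 28.3%) in untagged RNA.

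Heat shock, histone and immediate early genes were lower at 5 than at 60 min. A gene length bias, by which genes that span less sequence are recovered less after 5 min, was argued against: matched on span as well as expression, heat shock genes, replication-dependent histones and immediate early regulators each lay at percentile 0. Steady synthesis, with tagged RNA of the heat shock genes accumulating at a constant rate, was argued against for 3 of 12 heat shock genes, whose 60 against 20 min ratio had a lower counting limit above 3-fold. For the other heat shock genes this limit cannot decide, because the ratio is relative to the median gene, whose tagged RNA also builds up. A difference in cell state between the culture labelled for 60 min and the others stays open: heat shock genes had a median of 0.86 in 60 against 20 min, and without unlabelled cells a response to the label and a difference between cultures cannot be told apart.

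In the 8 protein-coding genes lowest in newly transcribed against total RNA, the fullest exon row held a median of 96.4% of total RNA reads (6.45 to 100%). Depth is argued against for 7 of the 8. Their upper counting limits lay at or below −1 when set to hold for 18551 protein-coding genes at the same time. Counting error alone in ENSG00000251357, with 2 reads against 18 and a limit of 0.0858, stays open. Picking the fullest exon moved the median of ribosomal protein genes by −0.00744, which argues against an effect of picking in those genes. Their fullest exon held a median of 35.6% of total RNA reads and they were not chosen as lowest. The test therefore cannot decide for the 8 genes. Reads of another short stable RNA inside a single exon may account for part of the pattern. Without that exon the median, with the pseudocount of 1, was −0.35. Still, 5 of the 8 stayed past a log2 of 1 in either direction, HRC and KISS1R as higher. In these 2 genes that exon held 100% of total RNA reads, so their values without it depend on the pseudocount. Both enter the median of −0.35. With the pseudocount, RPL13A went from −3.30 to −1.48 without the annotated snoRNA rows, within the quartiles of ribosomal protein genes. LBR, also with the pseudocount, went from −3.22 to −0.48 from exon rows alone, where 819 of its 930 total RNA reads lay beyond the exon rows. What those reads are stays open, and no biological explanation was tested.

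Last introns kept more of their 5 min ratio at 60 min than first introns, by 15.4 percentage points (13.1 to 18.1). Intron length is argued against, since at the same mix of lengths the difference was 14.1 points (12.2 to 16.0). The authors' gene value may account for it, since the gene row averages over exons that polymerases had not yet reached at 5 min: relative to the exon rows on either side the difference was −2.65 points (−6.98 to 1.41). With both adjustments it was −4.00 points (−7.14 to −1.21), so a small difference in the other direction stays open.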

How the results depend on the processing

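No paired analysis was possible because each group holds a single library. The rule of size, the lists and the main settings were fixed before the data were examined; counts restricted to genes with 50 or more reads, pooled intron ratios, exon rows in place of gene rows for the intron ratios, lists without centring or centred on genes with 50 or more reads, snoRNA hosts without short RNA rows, and the fit without mitochondrial genes were chosen after seeing the data. Of 439 alternative values for 74 results, 383 kept direction, except some medians near 0, and stayed on the same side or within 1.5 times. Of the rest 38 moved, 4 values placed a list median no longer apart and 14 newly apart, some for the same list, and 0 reversed a call. Lists without centring or centred on genes with 50 or more reads could not change place, because such a shift moves a list and its random lists alike. Those values are counted among the 383 and are no check of the place. With a trimmed mean the place could change only through the draw of random lists. Counts, and values without replicate spread or a binomial interval were taken to move past 1.5 times the value in the report. With a pseudocount of 5 the genes higher and lower were 475 and 1190 in newly transcribed against total RNA, 1561 and 784 in untagged against newly transcribed RNA, and 441 and 581 in 5 against 60 min. Fewer genes were tested at RPKM 5 (898 and 1434, 1614 and 1528, 816 and 490), among protein-coding genes of 500 nt or more (680 and 906, 1344 and 1479, 696 and 490) and with 50 or more reads (218 and 542, 865 and 475, 121 and 657). The settings at RPKM 5 and on protein-coding genes were also centred anew, on −0.86 at RPKM 5 in place of −0.42 in 5 against 60 min. On the main centring, protein-coding genes of any length were 678 and 977, 1630 and 1277, and 412 and 880. Centred on the genes with 50 or more reads themselves, 340 were higher and 294 lower in 5 against 60 min, so the excess of lower genes there depends on the centring. A pseudocount of 0.1 gave 5091 higher in untagged RNA and 2932 lower at 5 min, no filter 2932 lower at 5 min, and no centring 4314 lower there. The median intron ratio, 0 in total and untagged RNA, was 5.13 and 1.496% from summed values and 6.08 and 1.82% pooled over introns; in total RNA it was 4.31% for introns of 1000 nt or more and 2.94% in genes of RPKM 5 or more. The log2 change of the shortest introns was −0.84 in genes of RPKM 5 or more, −0.67 for introns above 0 and −1.08 pooled, and that of last introns −1.04 in genes of RPKM 5 or more. The cause of the shifts was not tested. At RPKM 5 NF-kappaB targets (0.31, percentile 91.35) and ribosomal proteins (−1.17, percentile 30.15) no longer lay apart in newly transcribed against total RNA, nor p53 targets in 5 against 60 min (−0.48, percentile 9; −0.61, percentile 3.15, at a pseudocount of 0.1). Some medians near 0 turned sign: on protein-coding genes of 500 nt or more mitochondrially encoded genes stood at 0.02 in newly transcribed against total RNA and zinc finger genes at 0.11 in 5 against 60 min, with trimmed mean centring histones at 0.01 in untagged RNA, and centred on genes with 50 or more reads oxidative phosphorylation at 0.09, snoRNA hosts at 0.07 and zinc finger genes at 0.21 in 5 against 60 min. The weights of the fit ranged from 0.285 to 0.398 and from 0.445 to 0.602, and list members at 0 reads, set to 3 reads, moved a list median by at most 0.14. Depth limits single genes: the median tested gene had 5 reads in untagged and 12 in newly transcribed RNA at 60 min.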

Other observations

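No test was chosen for the values given here. Small RNAs differed in their share of gene reads between the libraries. snRNAs took 0.0830% (Wilson interval 0.0768 to 0.0897%) at 5 min, 0.0444% (0.0403 to 0.0488%) at 60 min and 0.163% (0.154 to 0.172%) in total RNA. Mitochondrial tRNAs took 0.0746% (0.0688 to 0.0809%) at 5 min and 0.498% (0.481 to 0.515%) in untagged RNA, and pseudogenes 0.920% (0.899 to 0.941%) at 5 min and 0.330% (0.317 to 0.344%) in untagged RNA. Of 467 rows of short non-coding RNAs 329 had reads and 123 had 50 or more. SNORD58A and SNORD58C stood at log2 ratios of 7.37 (6.87 to 7.92) and 8.42 (7.69 to 9.26) in untagged against newly transcribed RNA, and SNORD41 at 1.92 (1.14 to 2.78) in 5 against 60 min.

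Of 309 short non-coding RNAs 6 stood in rising and 22 in falling order over the 5 labelling times, where a random order gives 0.833% each, against 31 and 1 of 411 zinc finger genes, 16 and 0 of 81 ribosomal protein genes and 8 and 0 of 36 proteasome subunits. These orders use the same centring as the other orders of labelling, and no other was tried. With the pseudocount of 1, SNHG12 and SNHG7, hosts of snoRNAs, stood at −1.28 and −1.41 in newly transcribed against total RNA. On that scale they stood at 0.88 and −0.83 without the short RNA rows inside their exons. Without rows and pseudocount they stood at 0.92 (0.49 to 1.36) and −0.86 (−1.14 to −0.58). By gene span, the median log2 ratio of 5 against 60 min was 0.26 in the first of 5 bins (median span 367 nt) and 0.04, −0.10, −0.11 and 0.03 in the longer ones.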
